A study of Homo sapiens with 22 samples.

How the data were processed

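Tumour tissue from xenografts of H3122, an ALK-positive human lung adenocarcinoma cell line, was profiled by bulk RNA sequencing in 22 samples. The samples form 6 groups from 2 hosts, NSG mice and hHGF-NSG mice, each therapy-naive or treated with alectinib, an ALK inhibitor, for 2 or 6 weeks. Total RNA was extracted with TRIzol, per the labels' protocols. The same samples have 1 table of human genes and 1 of mouse genes, since the reads were mapped to hg38 (GRCh38) and to mm10, per the submitters' processing notes. The notes also name DESeq2 without a role. The aligner, the gene annotation and how reads of 1 species were kept out of the other table are not given in the sources used here. The values in both tables are FPKM per gene as deposited, per the file headers. The human table lists 58735 genes, of which 19951 are protein coding, and the mouse table lists 54532 genes, of which 22046 are protein coding. Of these, 1741 human and 203 mouse genes share a symbol with another gene and were not named.

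The human table gave values for all 22 samples, with 4 per NSG group, 3 hHGF-NSG naive, 4 hHGF-NSG 2 weeks and 3 hHGF-NSG 6 weeks. The mouse table was used for 20 samples. NSG naive replicate 2 and NSG 6 weeks replicate 4 were not analysed there, which leaves 3 libraries in each of these groups. The labels do not say that the samples came from separate animals, so all p-values measure the spread between these samples. No pair of replicates had reads within counting noise of each other: the chi-square per degree of freedom was 4.3 or more in human and 4 or more in mouse reads.

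Whole reads were recovered from the steps of the low FPKM values and each gene's length, and 100% of the values came out whole within a tolerance of 0.05. The recovered totals were 10688632 to 19065656 human reads and 895826 to 5766509 mouse reads per library. The library size behind the deposited FPKM was a scaled one: the ratio of that size to the plain total was 0.876 to 1.111 in the human table and 0.947 to 1.106 in the mouse table. With 0 reads, up to 3 reads per library cannot be excluded, for counting error only.

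Genes at FPKM of 1 or more in at least 3 samples were tested, 16029 human and 14287 mouse genes. The values were transformed to log2(FPKM + 1), and a fold change on this scale understates the change of genes with low values. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all samples of a table, with empirical Bayes moderation and a mean-variance trend. The tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. The comparisons were 2 weeks and 6 weeks against naive in each host, hHGF-NSG against NSG in each state, 6 weeks against 2 weeks averaged over the hosts, and an F-test of whether the response to treatment differed between hosts. Exact two-sided permutation tests compared the mean log2(FPKM + 1) of human HGF between hosts and the share of mouse reads among all recovered reads. The count of genes called in both hosts is given beside the product of both counts over the number of genes tested, as the hosts share no control library. The fit used 1 spread per gene for both hosts, so their calls are not fully independent and this product, given below as chance, may be too low.

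The design, the named genes rule, 24 human and 21 mouse gene lists and 5 alternatives were fixed before the data were examined. Lists with 4 or more tested members were tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation. These p-values were adjusted over 152 human tests and 144 mouse tests. The genes named below have a symbol that is unique in its table and code for protein. The rule took HGF and MET, with Hgf and Met in the mouse table. For each time against naive it took the 10 genes per direction with the largest smaller change of both hosts, among genes called in both, with no overlap between the samples and a mean FPKM of at least 5 in the higher group. For each host comparison and for 6 weeks against 2 weeks it took the 5 largest changes per direction under the same conditions. For the difference in response it took up to 5 called genes with the smallest p, and for each gene list up to 4 members, the largest changes among called members or, with none called, the highest mean. Some genes that this rule took are not reported here, nor were they screened for libraries far from the others, while the counts and list tests include them.

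The 5 alternatives were a pseudocount of 0.1, no filter on low values, rescaling each sample by its median ratio, the replicate number as a block, and leaving out each sample in turn. Added after seeing the data were limma voom on the recovered reads and, for the mouse table, reads thinned to the smallest library. Lists of multiciliated cell and circadian clock genes were also chosen after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the tables and figures.

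The steps were tested on simulated reads for the real libraries, with 200 genes changed by a known fold. Treatment gave far more calls in the real data, so the values below need not hold there. For human NSG 2 weeks against naive, 64.1% of the genes changed by 2-fold (15547 genes tested) and 89.7% of those changed by 4-fold (15515 tested) were called. For human hHGF-NSG 6 weeks the shares were 63.6% (15608) and 82.7% (15593). For mouse NSG 2 weeks they were 34.2% (14308) and 74.3% (14333), and for mouse hHGF-NSG 6 weeks 25.7% (14310) and 69.9% (14302). Between 2 and 16 unchanged genes were called.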

Results

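Human reads of the xenografts were taken to stand for the H3122 tumour cells and mouse reads for the host tissue around them. NSG and hHGF-NSG hosts were compared therapy-naive, after 2 weeks and after 6 weeks of alectinib. Means of FPKM are given with the standard deviation (SD) of the samples and log2 changes with their standard error (SE). Where 2 values stand together, NSG comes before hHGF-NSG. The human comparisons used 4 samples per NSG group and 3, 4 and 3 in hHGF-NSG, the mouse ones 3, 4 and 3 in each host. Human libraries held 14821038 to 19065656 reads in NSG naive, 11852085 to 16364175 at 2 weeks and 11934313 to 16329855 at 6 weeks, and 15439437 to 16671918, 14854822 to 17182482 and 10688632 to 14376750 in the hHGF-NSG groups. Mouse libraries held 895826 to 2018939, 2255880 to 3049385 and 2594895 to 3340218 reads in NSG and 1127966 to 2471749, 1639063 to 3421604 and 4356095 to 5766509 in hHGF-NSG, so the mouse depth was larger at 6 weeks than in naive tumours.

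The mean share of mouse reads was larger after treatment in both hosts, without passing the test. In NSG the mean was 7.94 ± 3.53% in naive tumours, 15.73 ± 3.41% at 2 weeks and 19.16 ± 2.51% at 6 weeks (SD, n = 3, 4 and 3). In hHGF-NSG it was 9.74 ± 3.41%, 12.86 ± 4.23% and 27.29 ± 2.6% (n = 3, 4 and 3). The exact two-sided permutation p for 2 weeks against naive was 0.0571 in NSG and 0.3143 in hHGF-NSG. For 6 weeks against naive the exact p was 0.1 in either host, the smallest value that 3 against 3 samples allow. Between the hosts the exact p was 0.5 in naive tumours, 0.3429 at 2 weeks and 0.1 at 6 weeks, and after adjustment over these 7 tests the values were 0.175 to 0.5, so no difference in share was called. Among the naive NSG libraries, the library labelled NSG naive replicate 1 had 11.99% mouse reads and the others 5.5% and 6.32%.

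**Figure D1:**
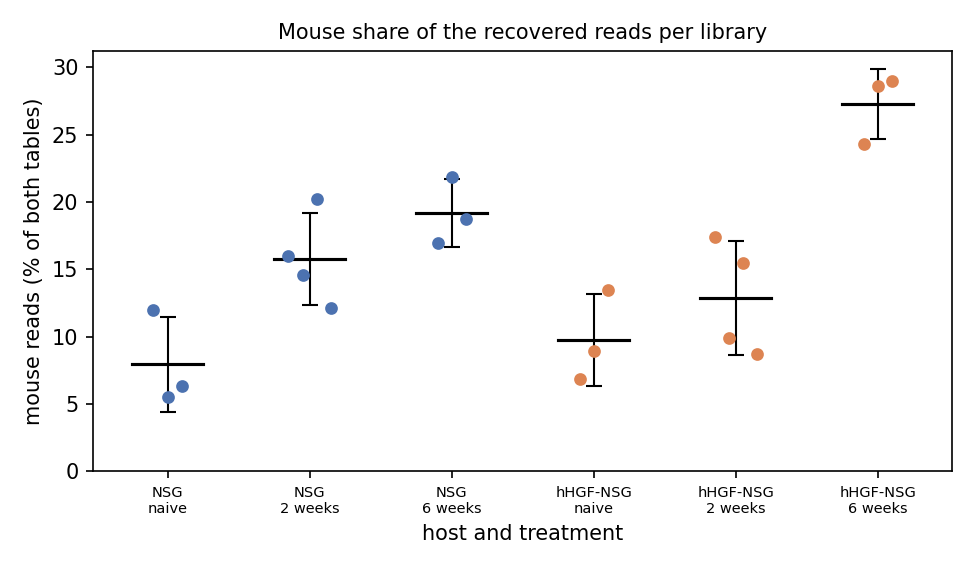
Share of mouse reads among all recovered reads (%) in each library, by host and time on alectinib. Each point is 1 library and the bar is the group mean.

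Human HGF (ENSG00000019991, hg38 chromosome 7, 81699008 to 81770438, minus strand), the ligand of the MET receptor and the gene that names the hHGF-NSG host, was read in all 10 hHGF-NSG libraries. The naive ones held 13, 28 and 44 reads (0.0978, 0.187 and 0.301 FPKM). Those at 2 weeks held 47, 33, 15 and 34 reads (0.276, 0.178, 0.0926 and 0.195 FPKM) and those at 6 weeks 79, 60 and 13 reads (0.549, 0.408 and 0.12 FPKM). In NSG tumours HGF had 0, 1, 0 and 1 reads at 2 weeks (0, 0.006, 0 and 0.00574 FPKM) and 1, 0, 6 and 0 reads at 6 weeks (0.00741, 0, 0.0468 and 0 FPKM). Of the naive NSG libraries, replicates 2, 3 and 4 held 0, 0 and 1 reads (0, 0 and 0.0061 FPKM), whereas the library labelled NSG naive replicate 1 held 43 reads (0.32 FPKM), as many as the hHGF-NSG libraries. HGF was higher in hHGF-NSG than in NSG at 2 weeks (0.185 ± 0.0752 against 0.00293 ± 0.00339 FPKM, SD, n = 4 and 4, difference 0.239 in log2(FPKM + 1), exact two-sided permutation p = 0.0286). It was higher at 6 weeks as well (0.359 ± 0.219 against 0.0135 ± 0.0224 FPKM, n = 3 and 4, difference 0.411, exact p = 0.0286). Naive tumours had 0.195 ± 0.102 against 0.0815 ± 0.159 FPKM (n = 3 and 4, difference 0.152, exact p = 0.3143), a comparison in which the library labelled NSG naive replicate 1 raised the NSG mean. The naive difference was 0.251 without that library and 0.089 without hHGF-NSG naive replicate 3 (exact p = 0.1 and 0.8). With all libraries the smallest exact p possible was 0.0286 in each state. With 3 against 3 it was 0.1, so the naive hosts did not overlap without the library labelled NSG naive replicate 1. Without any 1 of the NSG 2 weeks replicates 1 to 4 the difference at 2 weeks was 0.237, 0.24, 0.237 and 0.24, each with exact p = 0.0571. At 6 weeks the differences without 1 library were 0.31 to 0.543, with the smallest exact p that these numbers allow, 0.1 without an NSG library and 0.0667 without an hHGF-NSG one, so no call was possible there.

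**Figure D2:**
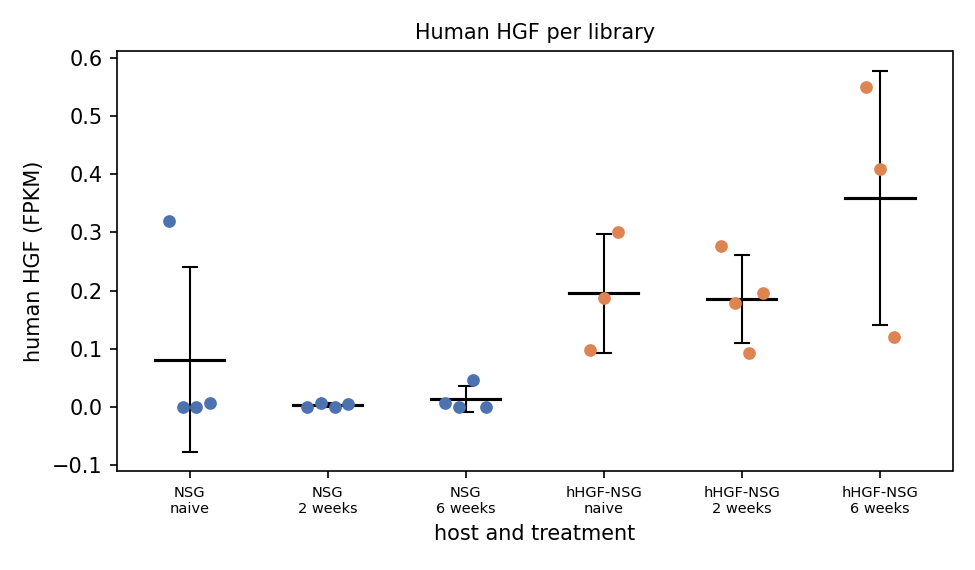
Human HGF in each library, as FPKM, by host and time on alectinib. Each point is 1 library.

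MET (ENSG00000105976, chromosome 7, 116672390 to 116798386, plus strand), the receptor of HGF, fell in the tumour cells on alectinib in both hosts. It went from 25.3 ± 1.84 to 10.4 ± 0.823 FPKM at 2 weeks in NSG (log2 change -1.20, SE 0.09, adjusted p = 7.05e-10). The fall was from 26.8 ± 2.13 to 8.9 ± 0.652 FPKM in hHGF-NSG (-1.49, SE 0.10, adjusted p = 8.58e-11). At 6 weeks MET stood at 12.2 ± 1.91 and 11.8 ± 0.649 FPKM (log2 changes -1, SE 0.09, and -1.11, SE 0.11, adjusted p = 1.1e-08 and 2.64e-08), 0.29 log2 units above 2 weeks (SE 0.07, adjusted p = 0.00361). The mouse Hgf gene (ENSMUSG00000028864, mm10 chromosome 5, 16553495 to 16620152, plus strand) had 2.7 ± 1.62, 2.07 ± 0.369 and 2.04 ± 0.557 FPKM in NSG and 0.944 ± 0.768, 0.998 ± 0.468 and 0.576 ± 0.371 in hHGF-NSG. Its differences between hosts were not called (-0.90, SE 0.35, adjusted p = 0.376 in naive tumours, -0.64, SE 0.30, adjusted p = 0.633 at 2 weeks and -0.96, SE 0.35, adjusted p = 0.79 at 6 weeks). Mouse Met had 1.48, 1.47 and 3.34 FPKM in NSG and 1.58, 2.38 and 4.16 in hHGF-NSG. It was called at 6 weeks against naive in hHGF-NSG (0.98, SE 0.30, adjusted p = 0.03). This call ended without any 1 hHGF-NSG naive replicate or hHGF-NSG 6 weeks replicate 2 or 3 (0.86 to 1.04). It ended also with a pseudocount of 0.1 (1.32) and without the filter (0.98), with adjusted p of 0.0197 to 0.12 over all settings.

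After 2 weeks of alectinib the tumour cells of both hosts gained transcripts of motile cilia genes and lost transcripts of hypoxia and cell cycle genes. ROPN1L (ENSG00000145491, chromosome 5, 10441524 to 10472029, plus strand), a radial spoke protein of motile cilia, rose from 0.621 ± 0.26 to 124 ± 16 FPKM in NSG (SD, n = 4 and 4, log2 change 6.27, SE 0.24, adjusted p = 1.27e-14). In hHGF-NSG it rose from 0.99 ± 1.09 to 147 ± 26 FPKM (n = 3 and 4, 6.34, SE 0.26, adjusted p = 3.95e-14). CDC20B, a gene expressed in cells that are forming many cilia, rose by 6.20 and 6.15 (SE 0.13 and 0.14), and TPPP3, a tubulin-binding protein, by 5.74 and 5.90. The tubulin gene TUBA4B rose by 5.49 and 5.59, the radial spoke gene RSPH1 by 5.22 and 5.36, C5orf49 by 5.14 and 5.24, WDR38 by 5.09 and 5.21, LRRC46 by 5.10 and 4.99 and LRRC10B by 4.91 and 4.94. SCGB1A1, the secretoglobin of club cells, was listed at 0 in every naive NSG library and at 40.6 ± 9.8 FPKM after 2 weeks. In hHGF-NSG SCGB1A1 rose from 0.076 ± 0.0659 to 51.3 ± 17.2 FPKM (5.55, SE 0.25, adjusted p = 1.36e-13).

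ADM (ENSG00000148926, chromosome 11, 10304680 to 10307397, plus strand), a vasodilator peptide induced by low oxygen, fell from 84.7 ± 10.9 to 0.888 ± 0.668 FPKM in NSG at 2 weeks (-5.55, SE 0.24, adjusted p = 7.21e-14). In hHGF-NSG it fell from 75.7 ± 9.55 to 0.25 ± 0.316 FPKM (-5.96, SE 0.26, adjusted p = 9.36e-14). IGFBP3, a binding protein of insulin-like growth factors, fell from 123 ± 39 to 1.77 ± 0.31 and from 193 ± 33.7 to 1.37 ± 0.468 FPKM (-5.42 and -6.36). The fatty acid desaturase SCD fell by 4.90 and 4.96, the amino acid transporter SLC7A5 by 4.55 and 4.61 and the lactate dehydrogenase LDHA by 4.14 and 4.41. The matrix genes TNC and LOX fell by 4.37 and 5.07 and by 4.28 and 4.41, the kinase anchoring protein AKAP12 by 4.34 and 4.69. The secreted mucin MUC5B fell by 4.42 and 4.33 and the ETS transcription factor ETV4 by 4.35 and 4.17. Among these 10 genes MUC5B had the largest adjusted p, 1.92e-11 in NSG and 9.46e-11 in hHGF-NSG. In NSG 8989 of 16029 human genes were called at 2 weeks, 4502 higher and 4487 lower, of which 1361 and 1082 changed at least 2-fold. In hHGF-NSG 8673 were called, 4414 higher and 4259 lower, of which 1505 and 1175 changed at least 2-fold. Called in both hosts were 3683 genes as higher (1239.7 by chance) and 3724 as lower (1192.2 by chance), and 2 genes were called in opposite directions. The log2 changes of the hosts had a correlation of 0.94 across genes, which are not independent replicates. Without the library labelled NSG naive replicate 1 the NSG count was 8541.

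At 6 weeks the human genes with the largest falls stayed low, while the gain in cilia genes was smaller than at 2 weeks. C2CD4C rose from 0.0557 ± 0.0727 to 43.9 ± 9.87 FPKM in NSG (SD, n = 4 and 4, log2 change 5.38, SE 0.21, adjusted p = 2.51e-14). In hHGF-NSG its FPKM went from 0.419 ± 0.0587 to 48.1 ± 17.2 (n = 3 and 3, 5.04, SE 0.24, adjusted p = 9.77e-13). Clusterin (CLU), a secreted chaperone, rose from 1.3 ± 0.294 to 54.1 ± 12.7 and from 0.994 ± 0.158 to 61.1 ± 22 FPKM (4.56 and 4.89), PIP by 4.23 and 4.37 and the Notch ligand DLL1 by 4.05 and 3.86. ROPN1L was still higher by 4.60 and 4.96, CDC20B by 4.60 and 4.24, TPPP3 by 4.29 and 5.04 and TUBA4B by 4.21 and 4.56. ADM fell by 5.98 and 5.66 against naive, IGFBP3 by 5.43 and 6.16, MUC5B by 5.89 and 4.62 and SCD by 5.34 and 4.97. SLC7A5 fell by 5.11 and 4.92, TNC by 4.86 and 5, LOX by 4.66 and 4.89 and AKAP12 by 4.42 and 4.62. RRM2, a subunit of ribonucleotide reductase, fell from 51.9 ± 3.38 to 1.4 ± 0.506 FPKM in NSG and by 4.49 and 4.48 in log2, and MYBL2, a transcription factor of the cell cycle, fell by 4.86 and 4.36. In NSG 9234 genes were called, 4612 higher and 4622 lower (1236 and 1247 at least 2-fold). In hHGF-NSG 8227 were called, 4144 higher and 4083 lower (1301 and 1202 at least 2-fold). Called in both hosts were 3337 higher (1192.3 by chance) and 3511 lower genes (1177.3 by chance), 17 were called in opposite directions, and the correlation across genes was 0.90. Without the library labelled NSG naive replicate 1 the NSG count was 8875.

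Cell cycle genes fell as a group: all 27 fell in both hosts at both times, with a median log2 change of -2.00 and -1.93 at 2 weeks and -2.51 and -2.36 at 6 weeks. MKI67, the proliferation marker, fell by 3.36 and 3.36 at 2 weeks and by 3.59 and 3.51 at 6 weeks. In the list of glycolysis and hypoxia genes 17 of 18 fell and 1 rose at 2 weeks in either host, and 17 and 16 fell at 6 weeks (median -2.55, -2.66, -2.58 and -2.69). All 14 cholesterol synthesis genes fell at 2 weeks in both hosts, and 13 and 14 fell at 6 weeks. Of 17 genes of MAPK pathway output 16 and 16 fell at 2 weeks and 13 and 15 at 6 weeks. DUSP6, a phosphatase that ERK signalling induces, fell from 128 ± 12.6 to 7.5 ± 1.66 FPKM in NSG at 2 weeks (-3.93, SE 0.24, adjusted p = 1.73e-11) and by 3.67 in hHGF-NSG. These 4 lists held with an estimated correlation in all 4 comparisons, with adjusted p of 0.00673 to 0.0111 for cell cycle, 0.00673 for glycolysis and hypoxia, 0.019 to 0.0204 for cholesterol synthesis and 0.0287 to 0.0482 for MAPK output. No other fixed human list did in these comparisons.

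Ribosome biogenesis genes were lower in most cases: 15 and 14 of 16 fell at 2 weeks and 16 and 14 at 6 weeks. The ribosome list had a preset adjusted p of 9.13e-07 to 5.2e-06, while the adjusted p was 0.197 to 0.21 with an estimated correlation. Of 9 mucous and gastric epithelium genes 1 rose and 7 and 8 fell at 2 weeks, and 1 rose and 8 and 8 fell at 6 weeks. The mucous list had a preset adjusted p of 4.52e-05 to 0.00417, and adjusted p = 0.171 to 0.307 with an estimated correlation. The trefoil peptide TFF3 fell from 1382 ± 269 to 361 ± 80.7 FPKM in NSG at 2 weeks (-1.94 and -1.77), TFF1 by 2.35 and 2.08 and MUC1 by 2.87 and 2.95. Of 8 mesenchymal genes 7 and 7 fell at 2 weeks and 4 and 6 at 6 weeks. The mesenchymal list had a preset adjusted p of 0.000653 to 0.0226, and adjusted p = 0.197 to 0.333 with an estimated correlation. N-cadherin (CDH2) fell by 1.61 and 1.58 at 2 weeks and by 2.25 and 2.41 at 6 weeks. VIM fell by 1.15 and 2.00 at 2 weeks and had -0.38 (adjusted p = 0.113) at 6 weeks in NSG. NF-kB genes fell in 5 and 6 of 8 cases at 2 weeks and in 5 and 5 at 6 weeks, where 1 rose in NSG. The NF-kB list had a preset adjusted p of 0.0204, 0.00452, 0.0623 and 0.0226, and adjusted p = 0.249 to 0.398 with an estimated correlation. The chemokine CXCL8 fell from 69.6 ± 6.28 to 5.29 ± 1.35 FPKM in NSG (-3.51 and -4.06). CXCL1 fell by 1.70 and 2.13 and CXCL2 by 1.5 and 1.58, whereas CCL20 fell by 1.25 in hHGF-NSG and had -0.50 (adjusted p = 0.0856) in NSG.

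Of 9 genes of the unfolded protein and amino acid stress responses 6 and 6 fell at 2 weeks and 6 and 4 at 6 weeks. The stress list had a preset adjusted p of 0.0175, 0.0226, 0.053 and 0.0647, and adjusted p = 0.249 to 0.339 with an estimated correlation. In the list of HGF processing and MET genes 4 and 3 of 8 fell at 2 weeks (5 in NSG when adjusted over the list alone), and 4 and 3 fell at 6 weeks, with 1 rise in hHGF-NSG. The HGF processing list had a preset adjusted p of 0.0683, 0.0434, 0.141 and 0.296, and adjusted p = 0.339 to 0.626 with an estimated correlation. The second of these became 0.0863 and 0.0569 without hHGF-NSG naive replicate 3 and hHGF-NSG 2 weeks replicate 3. Alveolar and club cell genes rose in 5 and 7 of 11 cases at 2 weeks and 5 and 7 at 6 weeks, while 1 and 1 and then 3 and 3 fell (preset adjusted p = 0.0552 to 0.17). SCGB3A1, an airway secretoglobin, rose from 32.4 ± 9.44 to 292 ± 83.5 FPKM in NSG at 2 weeks (3.14 and 3.72). Among 9 BCL2 family genes 5 rose and 2 fell in either host at 2 weeks, and 4 and 5 rose and 1 and 2 fell at 6 weeks (preset adjusted p = 0.121 to 0.227).

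Receptor tyrosine kinases moved in both directions, with 7 and 6 of 13 higher and 5 and 6 lower at 2 weeks and 7 and 7 higher and 6 and 5 lower at 6 weeks. RET rose from 1.62 ± 1.09 to 12.7 ± 3.14 FPKM in NSG at 2 weeks (2.44 and 3.10), KIT by 2.07 and 2.42, ERBB2 by 1.54 and 1.73 and the insulin receptor INSR by 1.34 and 1.26. Of 4 EGFR family ligands 1 rose and 3 fell at 2 weeks in either host, and at 6 weeks 1 rose and 1 and 3 fell. Of 10 FOXO targets 4 and 4 rose and 4 and 4 fell at 2 weeks, and 6 and 4 rose and 3 and 2 fell at 6 weeks. In the epithelial list of 11 genes 1 and 2 rose and 6 and 7 fell at 2 weeks, and 2 and 2 rose and 5 and 4 fell at 6 weeks. Of 8 YAP and TEAD targets 4 and 2 rose and 4 and 3 fell at 2 weeks, and 4 and 3 rose and 3 and 4 fell at 6 weeks.

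Interferon response genes rose in 3 and 5 of 15 cases and fell in 4 and 3 at 2 weeks, and rose in 6 and 8 and fell in 3 and 1 at 6 weeks (preset adjusted p = 0.935, 0.783, 0.528 and 0.0918). IFI6 rose from 11.8 ± 4.01 to 42.2 ± 23.1 and 107 ± 71.3 FPKM in hHGF-NSG (1.66, SE 0.46, adjusted p = 0.00442, and 2.93, SE 0.49, adjusted p = 4.29e-05). In NSG it had 28.6 ± 13.4, 34.2 ± 14.7 and 50.1 ± 8.83 FPKM (0.31, adjusted p = 0.563, and 0.93, adjusted p = 0.0675). IFIT1, IFIT2 and MX1 rose at 6 weeks by 0.84 and 1.28, 1.07 and 0.96 and 0.57 and 1.04. Of 10 genes of MHC class I presentation 1 and 0 rose and 3 and 3 fell at 2 weeks, and 3 and 5 rose and 2 and 2 fell at 6 weeks. TAP2 fell by 0.70 and 0.71 at 2 weeks, and HLA-E rose by 0.59 and 0.76 at 6 weeks, as did PSMB8 by 0.68 and 0.84. No MHC class II, leukocyte or skeletal muscle marker of the human lists passed the filter. Among the markers of other tissues, the fibroblast gene LUM fell from 12.2 ± 3.54 to 0.624 ± 0.216 FPKM in NSG at 2 weeks (-3.00 and -3.04), COL1A1 by 1.21 and 2.55 and COL5A1 by 0.97 and 2.09. How mouse reads were kept out is not given.

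**Figure D3:**
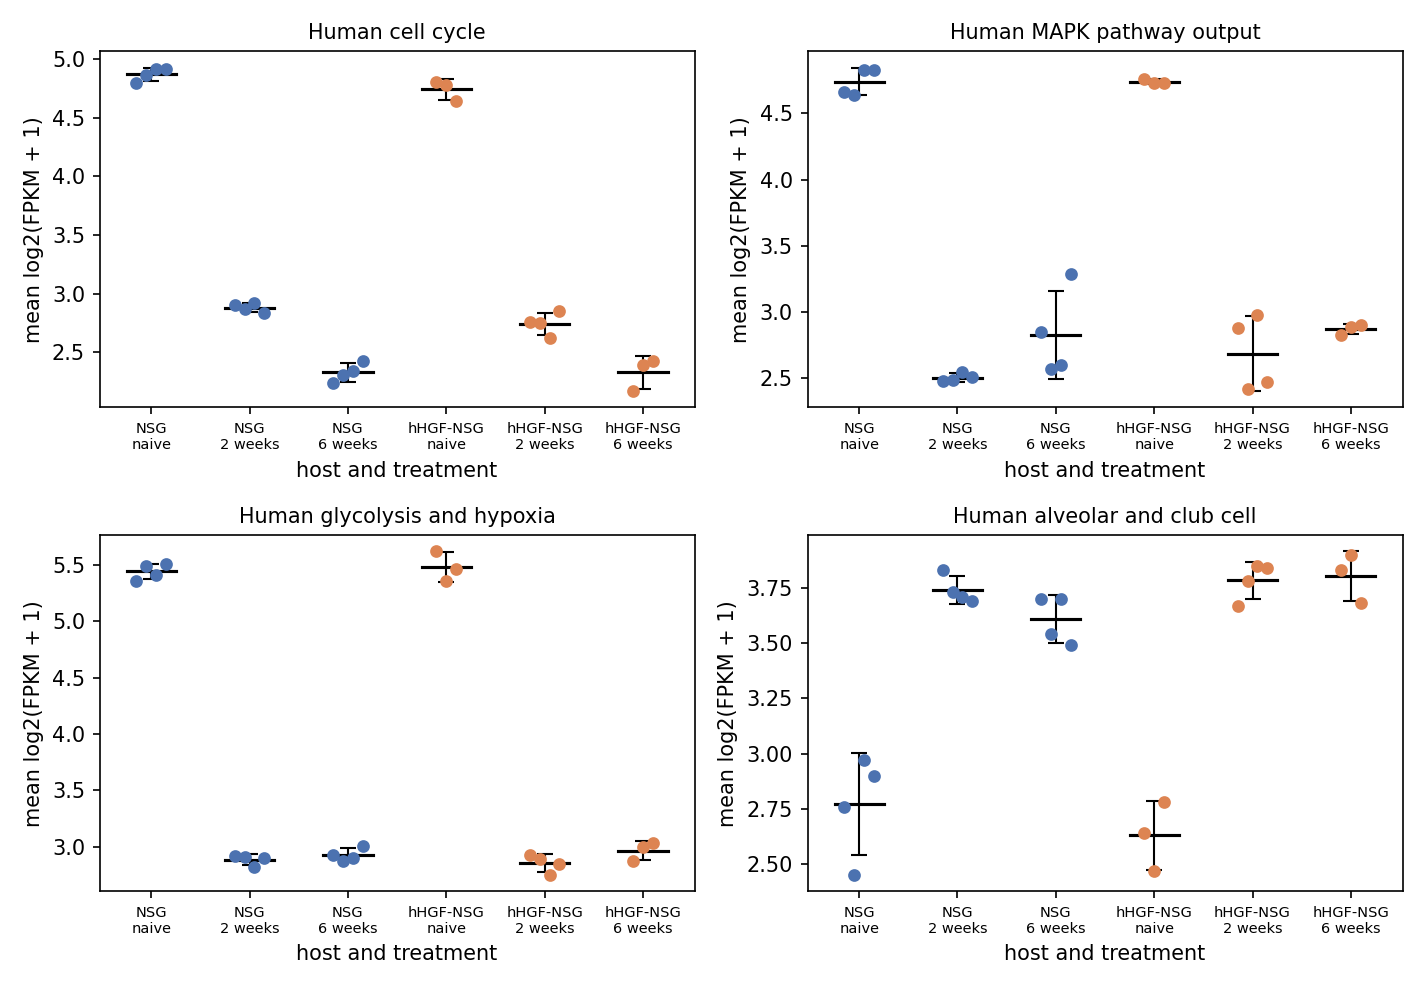
Mean log2(FPKM + 1) of 4 human gene lists in each library. Each point is 1 library, by host and time on alectinib.

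Between 2 and 6 weeks, genes under circadian control rose in the tumour cells and cilia genes fell. Averaged over the hosts, the clock repressor NR1D1 rose by 2.62 (SE 0.13, adjusted p = 8.65e-11), from 6.69 ± 0.812 to 40.2 ± 8.14 FPKM in NSG and from 4.99 ± 0.693 to 43.6 ± 15.4 in hHGF-NSG. The clock output factors TEF and DBP rose by 2.04 and 1.95, the transcription factor ATOH8 by 1.71 and IGFBP4 by 1.68. WDR38 fell by 1.95, HIST2H3D by 1.92, CCDC188 by 1.92, CROCC2, a homologue of the ciliary rootlet gene, by 1.90 and AC007906.2 by 1.86. ROPN1L and CDC20B fell by 1.52 and 1.75. In this comparison 3709 human genes were called, 1582 higher and 2127 lower (46 and 225 at least 2-fold). Of 27 cell cycle genes 17 fell (22 when adjusted over the list alone), which held with an estimated correlation (adjusted p = 0.0349). Interferon response genes rose in 6 and fell in 1 of 15 cases (11 and 1 over the list alone). Receptor tyrosine kinases rose in 6 of 13, FOXO targets in 5 of 10 and MHC class I genes in 4 of 10, and mucous genes fell in 6 of 9 (7 over the list alone). In this order, the 5 lists had preset adjusted p of 0.0012, 0.0209, 0.00724, 0.00471 and 0.000582. With an estimated correlation their adjusted p was 0.312, 0.333, 0.289, 0.287 and 0.225. Cholesterol genes rose in 1 and fell in 4 of 14 cases and HGF processing genes rose in 2 of 8 (preset adjusted p = 0.0373 and 0.0499, adjusted p = 0.387 and 0.343 with an estimated correlation). The cholesterol result ended without NSG 2 weeks replicate 3 (0.0565), NSG 6 weeks replicate 2 (0.0696) or hHGF-NSG 2 weeks replicate 1 (0.0541). That of HGF processing ended without NSG 2 weeks replicates 1, 3 and 4 (0.0672, 0.0565 and 0.0666), NSG 6 weeks replicate 4 (0.0505), hHGF-NSG naive replicate 3 (0.0546), hHGF-NSG 2 weeks replicates 2 and 3 (0.0564 and 0.0794) or hHGF-NSG 6 weeks replicate 2 (0.0761).

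Few human genes were called between the hosts. In naive tumours 3 genes were called, 2 higher and 1 lower in hHGF-NSG (unadjusted p < 0.05 for 1427 genes). The glucose transporter SLC2A3 (ENSG00000059804, chromosome 12, 7919230 to 7936275, minus strand) had 6.42 ± 0.807 FPKM in NSG and 11.9 ± 1.7 in hHGF-NSG (SD, n = 4 and 3, log2 difference 0.79, SE 0.11, adjusted p = 0.00498). ST6GALNAC1 (ENSG00000070526, chromosome 17, 76624761 to 76643838, minus strand), a sialyltransferase of mucin-type glycans, had 50.2 ± 3.14 and 35.5 ± 1.02 FPKM (-0.49, SE 0.07, adjusted p = 0.0173). The third, RNA5SP283, is a 5S RNA pseudogene whose reads may belong to other copies, and was chosen after its values were seen. The call of SLC2A3 ended without NSG naive replicate 4 (0.75, adjusted p = 0.0538) and hHGF-NSG naive replicate 1 (0.69, adjusted p = 0.0874) and with a pseudocount of 0.1 (0.88, adjusted p = 0.00114 to 0.395 over all settings). That of ST6GALNAC1 ended without NSG naive replicate 3 or 4, without any 1 of the 3 hHGF-NSG naive replicates and with the replicate block (adjusted p = 0.00192 to 0.0958 over all settings), while the difference stayed at -0.51 to -0.48.

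At 2 and 6 weeks no human gene was called between the hosts by limma (unadjusted p < 0.05 for 681 and 1946 genes), and limma voom called 4, 0 and 2 genes in the 3 states. Leaving out the library labelled NSG naive replicate 1 gave 40 called genes in naive tumours, leaving out NSG naive replicates 3 and 4 gave 1 and 0 and leaving out hHGF-NSG naive replicates 1 and 2 gave 0 and 1. At 2 weeks 1 gene was called without NSG 2 weeks replicate 2 and 1 without hHGF-NSG 2 weeks replicate 4. At 6 weeks 2, 3, 3, 8, 3 and 3 genes were called without NSG 2 weeks replicate 2, NSG 2 weeks replicate 3, NSG 6 weeks replicate 1, NSG 6 weeks replicate 3, hHGF-NSG 6 weeks replicate 1 and hHGF-NSG 6 weeks replicate 2. No human gene had a response that differed between hosts (0 called, unadjusted p < 0.05 for 1639, and 0 by limma voom). In that test 7, 1, 1 and 1 genes were called without the library labelled NSG naive replicate 1, NSG naive replicate 2, NSG 2 weeks replicate 1 and hHGF-NSG 6 weeks replicate 1.

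No member of the human lists was called between the hosts. With the preset correlation, cell cycle genes were lower in hHGF-NSG in naive tumours and at 2 weeks (median -0.12 and -0.13, adjusted p = 0.000934 and 1.17e-06, adjusted p = 0.333 and 0.199 with an estimated correlation). Adjusted over the list alone, 2 cell cycle genes were lower at 2 weeks. Mesenchymal genes had a median of 0.38 in naive tumours (adjusted p = 0.00894, with 2 higher over the list alone) and mucous genes -0.43 (adjusted p = 0.00572), with adjusted p = 0.295 and 0.312 with an estimated correlation. The other list results at 2 weeks were HGF processing and MET with a median of -0.19 (adjusted p = 0.00274), mucous genes (0.016), mesenchymal genes (0.0226) and epithelial genes (0.0324), where the adjusted p was 0.199, 0.343, 0.333 and 0.454 with an estimated correlation. Without hHGF-NSG naive replicate 3 the naive results of cell cycle, mesenchymal and mucous genes ended (preset adjusted p = 0.118, 0.268 and 0.0891), and that of mesenchymal genes also without NSG naive replicate 2 (0.0532). At 2 weeks that of mucous genes ended without NSG replicate 1 (0.101) or hHGF-NSG replicate 2 (0.154). That of mesenchymal genes ended without NSG replicates 2 and 4 (0.0524 and 0.0888) or hHGF-NSG replicate 3 (0.113). That of epithelial genes ended without NSG replicates 2 and 4 (0.172 and 0.0696) or hHGF-NSG replicates 2 and 3 (0.171 and 0.159). At 6 weeks no fixed human list was called between the hosts.

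In the host tissue, Penk, Apod and the hedgehog gene Gli1 rose after 2 weeks of alectinib, while Gzme, Gzmd, Mmp13 and Mmp10 fell. Penk (ENSMUSG00000045573, chromosome 4, 4133531 to 4138819, minus strand), the precursor of enkephalins, rose from 5.16 ± 1.24 to 96.3 ± 27.7 FPKM in NSG (SD, n = 3 and 4, log2 change 3.94, SE 0.41, adjusted p = 1.27e-05). In hHGF-NSG Penk went from 5.48 ± 5.6 to 103 ± 22.3 FPKM (n = 3 and 4, 4.32, SE 0.41, adjusted p = 6.53e-06). The lipid carrier Apod rose from 58 ± 41.3 to 485 ± 94 and from 50.4 ± 14.3 to 681 ± 151 FPKM (3.28 and 3.74). Gli1, the transcription factor and target of hedgehog signalling, rose from 0.185 ± 0.168 to 14.1 ± 5.11 and from 0.538 ± 0.576 to 13.3 ± 3.14 (3.61 and 3.25). Galr2, a galanin receptor, rose by 3.06 and 3.31, Tmem132c by 2.95 and 2.92, the clock output gene Dbp by 3.39 and 2.62 and the matrix genes Omd and Fbln7 by 2.52 and 3.14 and 3.09 and 2.44. Tcf15 rose by 2.73 and 2.90, a call that ended in NSG with limma voom (3.35, adjusted p = 0.000153 to 0.069 over all settings). Adrb3, the beta-3 adrenergic receptor of fat cells, rose by 2.39 and 2.39. These calls ended with limma voom and without NSG naive replicate 4 (2.00, adjusted p = 0.0727) or hHGF-NSG naive replicate 1 (1.66, adjusted p = 0.0974), in ranges of 0.00431 to 0.121 and 0.00602 to 0.0974.

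Gzme, a granzyme of a family of similar genes that may share reads, fell from 108 ± 22.4 to 1.83 ± 1.45 and from 119 ± 53.8 to 1.39 ± 1.22 FPKM (-5.41 and -5.73, SE 0.43 and 0.43, adjusted p = 4.24e-07 and 3.87e-07). Gzmd fell from 53 ± 26.6 to 0.411 ± 0.565 FPKM in NSG and was listed at 0 in all hHGF-NSG libraries at 2 weeks. The matrix proteases Mmp13 and Mmp10 fell by 4.33 and 4.71 and by 3.25 and 3.46, the keratin Krt14 by 3.16 and 3.15, the arginase Arg1 by 3.49 and 2.95 and the growth factor Pgf by 2.92 and 3.60. S100a9, a calcium-binding protein of neutrophils, fell by 2.97 and 4.89, and its partner S100a8 by 3.18 and 3.69. The NSG calls of both ended with a pseudocount of 0.1 (-3.04 and -4.09, adjusted p = 0.000109 to 0.102 and 0.00388 to 0.0843 over all settings), and that of S100a8 without NSG naive replicate 3 (-2.95, adjusted p = 0.0567). The basophil protease Mcpt8 had 7.89 ± 2.1 FPKM in naive NSG tumours and was listed at 0 in all NSG libraries at 2 weeks, and it fell by 3.67 in hHGF-NSG.

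In NSG 1115 of 14287 mouse genes were called at 2 weeks, 475 higher and 640 lower (233 and 332 at least 2-fold). In hHGF-NSG 1008 were called, 499 higher and 509 lower (244 and 250 at least 2-fold). Both hosts shared 170 higher (16.6 by chance) and 282 lower genes (22.8 by chance), none in opposite directions, with a correlation of 0.56 across genes. The NSG count was 1089 without the library labelled NSG naive replicate 1, and 734 and 655 without NSG 2 weeks replicates 1 and 3. The hHGF-NSG count was 483, 644, 638 and 649 without hHGF-NSG naive replicates 1 and 2 and hHGF-NSG 2 weeks replicates 1 and 3. Without hHGF-NSG naive replicate 1 the shared genes were 103 and 175, and without NSG 2 weeks replicate 3 the shared higher genes were 111.

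After 6 weeks Cox8b, Dgat2 and Cidea rose in the host tissue, while Actg2 and Cnn1 fell. Cox8b, a cytochrome oxidase subunit of brown fat and muscle, rose from 1.66 ± 2.87 to 116 ± 8.87 FPKM in NSG (SD, n = 3 and 3, log2 change 6.00, SE 1.06, adjusted p = 0.000722). In hHGF-NSG Cox8b went from 6.15 ± 6.61 to 112 ± 39.3 FPKM (n = 3 and 3, 4.60, SE 1.06, adjusted p = 0.00528). Dgat2, an enzyme of triglyceride synthesis, rose from 11 ± 7.97 to 252 ± 31.6 and from 25.2 ± 11.9 to 420 ± 162 FPKM (4.58 and 4.07). The lipid droplet gene Cidea rose by 4.72 and 3.73, Nnat by 3.97 and 4.61, Ces1d by 3.93 and 3.75, Sncg by 3.61 and 3.61 and Adrb3 by 4.46 and 3.94. Penk and Apod stayed higher by 3.8 and 3.98 and by 3.91 and 3.88, Dbp by 4.30 and 4.45, Fbln7 by 4.11 and 3.07 and Omd by 3.63 and 3.50. Gli1 rose by 2.40 and 1.94 against naive. Actg2, the smooth muscle actin, fell from 107 ± 40.9 to 4.59 ± 2.42 and from 125 ± 47 to 3.89 ± 2.64 FPKM (-4.28 and -4.76) and calponin (Cnn1) by 3.78 and 3.57. Gzme was listed at 0 in all NSG libraries at 6 weeks, as was Gzmd, and fell by 6.45 in hHGF-NSG, and Gzmc fell by 3.74 and 4.38. Mcpt8 was listed at 0 in all libraries of both hosts at 6 weeks. S100a9 fell by 6.61 and 4.83, Mmp13 by 4.58 and 4.52, Mmp10 by 3.99 and 3.44, the endothelial proteoglycan Esm1 by 3.76 and 3.52, Cemip, a hyaluronan-degrading protein, by 3.40 and 3.54 and Pgf by 3.39 and 3.48. S100a8 fell by 4.71 and 3.22, where the hHGF-NSG call ended without hHGF-NSG naive replicate 1 (-2.43, adjusted p = 0.0586) and with a pseudocount of 0.1 (0.00126 to 0.073 over all settings). In NSG 2486 mouse genes were called, 1259 higher and 1227 lower (764 and 638 at least 2-fold), and 2583 without the library labelled NSG naive replicate 1. In hHGF-NSG 2541 were called, 1381 higher and 1160 lower (842 and 558 at least 2-fold), and 1641 without hHGF-NSG 6 weeks replicate 2. Both hosts shared 754 higher (121.7 by chance) and 743 lower genes (99.6 by chance), 1 gene was called in opposite directions, and the correlation across genes was 0.74.

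Of 23 mouse cell cycle genes 9 and 10 fell at 2 weeks (17 and 15 over the list alone) and 21 and 19 at 6 weeks (23 and 20 over the list alone). At 6 weeks the list held with an estimated correlation (adjusted p = 0.0179 and 0.0321), and at 2 weeks it did not (0.0732 and 0.0732). Mki67 fell by 0.96 and 1.15 at 2 weeks and from 8.33 ± 2.06 to 0.351 ± 0.115 and from 4.99 ± 1.15 to 0.496 ± 0.143 FPKM at 6 weeks (-2.77 and -1.99). At 6 weeks Ccna2, Cdc20 and Ccnb2 fell by 2.93 and 2.28, 2.93 and 1.95 and 3.11 and 1.45. All 10 adipocyte genes rose in both hosts at 6 weeks, and 0 and 1 at 2 weeks (0 and 10 over the list alone). Their preset adjusted p was 0.0038 and 4.39e-05 at 2 weeks and 1.06e-08 and 1.09e-08 at 6 weeks, and the adjusted p was 0.518, 0.36, 0.217 and 0.217 with an estimated correlation. In NSG at 2 weeks the preset value was 0.167 without NSG naive replicate 4. Leptin (Lep) rose by 3.14 and 3.37 at 6 weeks, the lipid droplet coats Plin1 and Plin4 by 3.37 and 3.03 and 2.51 and 3.17 and resistin (Retn) by 3.09 and 2.82. Of 7 neutrophil genes 5 and 4 fell at 2 weeks and 6 and 4 at 6 weeks. The neutrophil list had a preset adjusted p of 1.25e-06 to 3.35e-05, and adjusted p = 0.0732, 0.0732, 0.0732 and 0.0981 with an estimated correlation.

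Myofibroblast and contractile genes fell in 1 and 2 of 11 cases at 2 weeks and in 5 and 7 at 6 weeks. The myofibroblast list had a preset adjusted p of 0.69, 0.00126, 0.000108 and 3.03e-07, and adjusted p = 0.882, 0.379, 0.288 and 0.189 with an estimated correlation. Acta2, the smooth muscle actin of myofibroblasts, fell from 633 ± 163 to 130 ± 17 FPKM in NSG at 6 weeks (-2.25 and -2.41) and Myl9 by 1.82 and 1.22. Extracellular matrix genes rose in 2 and 1 of 11 cases and fell in 2 and 6 at 2 weeks, and 6 and 7 fell at 6 weeks. The matrix list had a preset adjusted p of 0.63, 0.0106, 3.74e-05 and 2.78e-07, and adjusted p = 0.866, 0.483, 0.288 and 0.184 with an estimated correlation. In hHGF-NSG at 2 weeks the preset value was 0.0515 without hHGF-NSG 2 weeks replicate 3. At 6 weeks Loxl2 fell by 2.26 and 2.37, Col5a1 by 1.72 and 1.95, Lox by 1.43 and 1.79 and Fbn1 by 1.35 and 1.72, while Col1a1 had -0.65 and -1.01 (adjusted p = 0.234 and 0.0617). Of 9 inflammatory fibroblast genes 5 and 2 fell at 2 weeks, and at 6 weeks 5 and 5 fell and 1 and 1 rose. The inflammatory fibroblast list had a preset adjusted p of 1.15e-05, 0.00102, 0.00441 and 0.0065, and adjusted p = 0.0732, 0.144, 0.199 and 0.217 with an estimated correlation. Fibroblast genes rose in 2 and 2 of 12 cases at 2 weeks and in 3 and 2 at 6 weeks, with none lower. The fibroblast list had a preset adjusted p of 0.000443, 0.288, 0.0627 and 0.77, and adjusted p = 0.288 for the first with an estimated correlation. Of 9 TGF-beta response genes 1 and 1 rose and 2 and 3 fell at 2 weeks, and 1 and 1 rose and 4 and 6 fell at 6 weeks. The TGF-beta list had a preset adjusted p of 0.523, 0.00467, 0.0859 and 0.000534, and adjusted p = 0.802, 0.36, 0.538 and 0.288 with an estimated correlation. Tgfb3 rose from 52.8 ± 2.93 to 142 ± 23.1 FPKM in NSG at 2 weeks (1.40 and 1.39), while Thbs1 fell by 2.02 and 2.63 at 6 weeks.

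Endothelial genes fell in 7 and 3 of 13 cases at 2 weeks and in 8 and 3 at 6 weeks, where 1 rose in hHGF-NSG. The endothelial list had a preset adjusted p of 7.55e-06, 0.00216, 3.79e-07 and 0.00722, and adjusted p = 0.149, 0.288, 0.11 and 0.36 with an estimated correlation. In hHGF-NSG at 6 weeks the preset value was 0.0523 without hHGF-NSG naive replicate 3. Pericyte genes fell in 5 and 3 of 7 cases at either time (preset adjusted p = 2.85e-05, 0.000521, 0.00015 and 0.00237, adjusted p = 0.0732, 0.122, 0.0981 and 0.175 with an estimated correlation). Of 14 macrophage genes 1 and 0 rose and 2 and 3 fell at 2 weeks, and 1 and 0 rose and 4 and 4 fell at 6 weeks. The macrophage list had a preset adjusted p of 0.0643, 0.0264, 0.0736 and 0.00633, and adjusted p = 0.538, 0.499, 0.538 and 0.401 with an estimated correlation. In hHGF-NSG at 2 weeks the preset value was 0.193 and 0.199 without hHGF-NSG naive replicate 1 and hHGF-NSG 2 weeks replicate 3. Dendritic cell and MHC class II genes rose in 1 and 0 of 9 cases and fell in 0 and 1 at 2 weeks, and rose in 2 and 0 at 6 weeks (preset adjusted p = 0.097 to 0.688). Of 6 mast cell genes 0 and 1 fell at 2 weeks and 1 and 1 at 6 weeks (preset adjusted p = 0.0537 to 0.69). Interferon response genes fell in 2 and 1 of 12 cases at 2 weeks and in 1 and 0 at 6 weeks (preset adjusted p = 0.00271, 0.113, 0.0969 and 0.65, adjusted p = 0.322 for the first with an estimated correlation). The first became 0.0628 without the library labelled NSG naive replicate 1. The only lymphocyte marker measured, Cd4, had 3.91 to 6.12 FPKM in the group means and was not called.

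Red blood cell genes fell in 4 of 5 cases in NSG at 2 and at 6 weeks and in 0 of 5 in hHGF-NSG (preset adjusted p = 2.05e-07, 0.00101, 0.0253 and 0.958 for NSG at 2 and 6 weeks and hHGF-NSG at 2 and 6 weeks). With an estimated correlation the adjusted p was 0.0732, 0.217, 0.379 and 0.977. In hHGF-NSG at 2 weeks the preset value was 0.15, 0.0576 and 0.0756 without hHGF-NSG naive replicates 1 and 2 and hHGF-NSG 2 weeks replicate 2. The globin Hba-a1 had 648 ± 125, 107 ± 23.5 and 179 ± 51.4 FPKM in NSG (-2.59 and -1.87) and 609 ± 336, 282 ± 138 and 512 ± 139 in hHGF-NSG (-1.02, adjusted p = 0.125, and -0.08, adjusted p = 0.93). Hba-a2 was listed at 0 in all treated hHGF-NSG libraries, and reads of the globin genes may be shared between copies. The list test of the difference in response between hosts, which was not among the fixed tests, gave a preset adjusted p of 1.57e-05 at 2 weeks and 2.85e-05 at 6 weeks, with adjusted p = 0.24 at both with an estimated correlation. No globin gene was called in the gene test.

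Of 11 receptor tyrosine kinase ligands 1 and 2 rose and 3 and 3 fell at 2 weeks, and 2 and 2 rose and 4 and 4 fell at 6 weeks (preset adjusted p = 0.247 to 0.44). Skeletal muscle genes fell in 2 and 1 of 4 cases at 2 weeks and in 1 and 1 at 6 weeks. The list had a preset adjusted p of 0.00334, 0.411, 0.0436 and 0.889 (0.186 and 0.326 for NSG with an estimated correlation). The NSG results rested largely on NSG naive replicate 4, whose list mean was 4.04 in log2(FPKM + 1) against 1.93 and 1.79 in the other naive NSG libraries. Without it the preset adjusted p was 0.0663 at 2 weeks and 0.374 at 6 weeks, and without NSG 6 weeks replicate 2 it was 0.058 at 6 weeks. Of 6 Schwann cell genes 1 and 0 fell at 2 weeks and none at 6 weeks (preset adjusted p = 0.0142 for NSG at 2 weeks, 0.317 with an estimated correlation and 0.0876 without NSG naive replicate 3). Among 3 keratinocyte genes Krt14 fell in both hosts at both times. The markers of tumour epithelium were low in the mouse table and 3 of 12 passed the filter. How human reads were kept out of the mouse table is not given in the sources used here. Of the fixed mouse lists, only cell cycle held with an estimated correlation, at 6 weeks in both hosts and between 2 and 6 weeks.

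**Figure D4:**
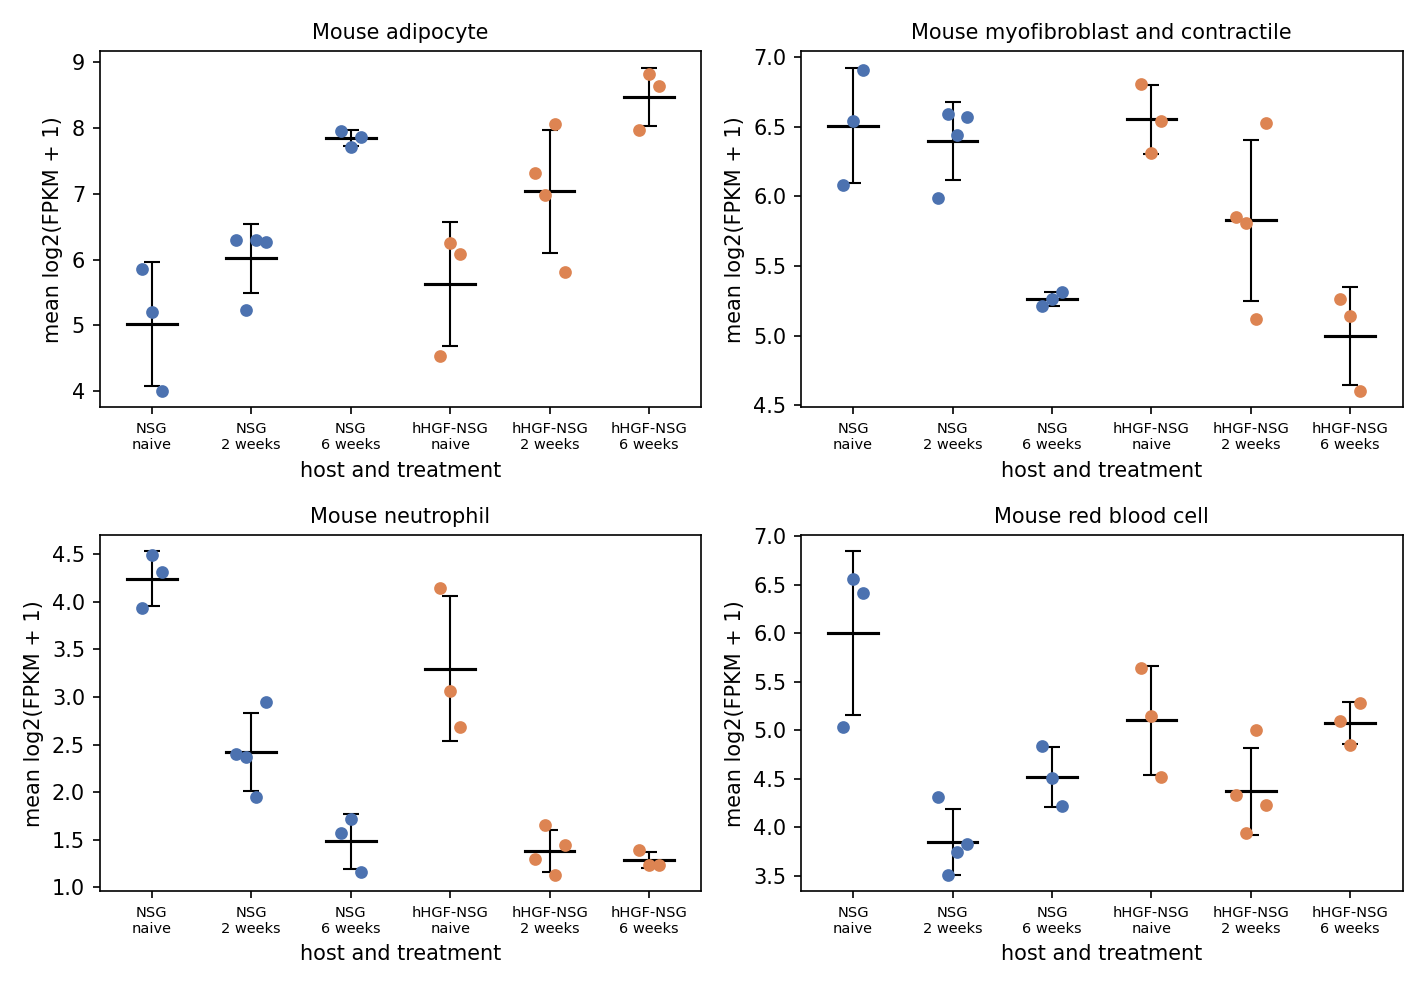
Mean log2(FPKM + 1) of 4 mouse gene lists in each library. Each point is 1 library, by host and time on alectinib.

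From 2 to 6 weeks, averaged over the hosts, Cyp2e1 and Rasd1 rose in the host tissue, while Col26a1 and Fbn2 fell. Cyp2e1, a cytochrome P450 of liver and fat, rose by 3.01 (SE 0.36, adjusted p = 5.86e-05), from 46.3 ± 11.4 to 531 ± 64.8 FPKM in NSG and from 138 ± 71.5 to 728 ± 263 in hHGF-NSG. Rasd1 rose by 2.61, Rprml by 2.55, Inmt by 2.52 and the retinoid-binding Rbp7 by 2.41. The collagen Col26a1 fell by 2.31 (SE 0.23, adjusted p = 1.47e-05), the fibrillin Fbn2 by 2.13, tenascin-C (Tnc) by 1.81, Ccnb2 by 1.63 and the transcription factor Snai1 by 1.58. In this comparison 1505 genes were called, 905 higher and 600 lower (308 and 89 at least 2-fold), 931 and 995 without hHGF-NSG 6 weeks replicates 2 and 3 and 944 with the replicate block. Of the lists, 19 of 23 cell cycle genes fell (20 over the list alone, adjusted p = 0.0179 with an estimated correlation) and all 10 adipocyte genes rose (preset adjusted p = 2.55e-09, adjusted p = 0.205 with an estimated correlation), of which Retn was not called without any 1 of 15 libraries (adjusted p up to 0.121) and Lep without any 1 of 9 (up to 0.0812). Extracellular matrix genes fell in 9 of 11 cases and myofibroblast genes in 5 of 11 (10 over the list alone), with preset adjusted p = 3.26e-10 and 1.06e-08 and adjusted p = 0.11 and 0.146 with an estimated correlation. Red blood cell genes rose in 3 of 5 cases and 1 of 9 TGF-beta response genes fell (preset adjusted p = 0.00524 and 0.0126, adjusted p = 0.288 and 0.412 with an estimated correlation). The TGF-beta value was 0.0827 without hHGF-NSG 6 weeks replicate 3.

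The host tissues differed in few genes, of which Tnn was called at both treated times in every setting tried. Tnn (ENSMUSG00000026725, chromosome 1, 160085029 to 160153580, minus strand), the matrix protein tenascin-N, was lower in hHGF-NSG at 2 weeks (35.7 ± 9.83 against 2.2 ± 0.869 FPKM, SD, n = 4 and 4, log2 difference -3.52, SE 0.33, adjusted p = 3.88e-05). At 6 weeks the difference remained (41.6 ± 7.42 against 1.75 ± 0.674 FPKM, n = 3 and 3, -3.97, adjusted p = 2.78e-05). Naive tumours had 36 ± 21.1 and 20.2 ± 6.08 FPKM. Hc, the complement component C5, was lower at 6 weeks (6.04 ± 0.586 against 0.796 ± 0.113 FPKM, -1.97, adjusted p = 3.67e-05). At 2 weeks S100a9 was lower by 3.54 (19.4 ± 10.2 against 0.767 ± 0.94 FPKM, adjusted p = 0.00221). Hbb-bt, a beta globin whose reads may be shared with its neighbours, was higher by 2.37 (4.55 ± 1.96 against 29.1 ± 14.2 FPKM, adjusted p = 0.00153). Higher at 2 weeks were also Pmvk, a kinase of the mevalonate pathway (2.18, adjusted p = 0.00576), the acid phosphatase Acp5 (1.04, adjusted p = 0.00675) and the adaptor Shc1 (1.03, adjusted p = 0.00307). In total 53 mouse genes were called between the hosts at 2 weeks (18 higher and 35 lower) and 36 at 6 weeks (10 higher and 26 lower), and 25 were called at both times. The counts were 76 and 54 without the library labelled NSG naive replicate 1.

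Other calls between the host tissues ended when a library was left out, although the log2 differences stayed similar. At 2 weeks the MHC class I gene H2-T23 (-2.76, adjusted p = 0.0129), of a family that may share reads, lost its call without NSG 2 weeks replicate 1 or 2 or hHGF-NSG 2 weeks replicate 3 (-2.71 to -2.61, adjusted p = 2.42e-05 to 0.0607 over all settings). Ndufs5 (-2.71, adjusted p = 0.0111) and Ifi44l (5.95 ± 3.64 FPKM in NSG and listed at 0 in every hHGF-NSG library, adjusted p = 0.0111) lost theirs without NSG 2 weeks replicate 1 (-2.51 and -2.32, adjusted p = 0.0564 and 0.057, with ranges of 0.0011 to 0.179 and 0.00178 to 0.057). Transferrin (Trf, 1.05, adjusted p = 0.037) was not called without any 1 of NSG 2 weeks replicates 1 to 4, hHGF-NSG 2 weeks replicates 1 to 3, NSG 6 weeks replicates 1 and 2 and hHGF-NSG 6 weeks replicate 1 (0.95 to 1.14, adjusted p = 0.0505 to 0.17). At 6 weeks Hbb-bt (2.07, adjusted p = 0.0246) and Ndufs5 (-2.88, adjusted p = 0.032) lost their calls without any 1 of NSG 6 weeks replicates 1 to 3 and hHGF-NSG 6 weeks replicates 1 to 3 (adjusted p = 0.0685 to 0.172 and 0.0685 to 0.248), with differences of 1.9 to 2.29 and -3.16 to -2.54. Trim12c (-1.90, adjusted p = 0.0124) did so without each of these except NSG replicate 3 (-1.92 to -1.81, adjusted p = 0.0631 to 0.0702) and Gbp2b (-2.17, adjusted p = 0.0167) without each except NSG replicate 1 (-2.29 to -1.89, adjusted p = 0.0589 to 0.118). Flad1 (1.33, adjusted p = 0.0357) and Kcnj15 (1.52, adjusted p = 0.0415) lost their calls without any 1 of these 6, as did 1500015O10Rik (1.33, adjusted p = 0.0357) except for hHGF-NSG replicate 3. The call of Flad1 ended also without NSG 2 weeks replicate 3 or hHGF-NSG 2 weeks replicate 4 (1.14 to 1.47, adjusted p = 0.0507 to 0.324). That of Kcnj15 ended without NSG naive replicate 4, NSG 2 weeks replicates 2 and 3, hHGF-NSG naive replicates 1 to 3 and hHGF-NSG 2 weeks replicates 1, 2 and 4 (1.27 to 1.72, adjusted p = 0.0508 to 0.339). That of 1500015O10Rik ended without NSG naive replicate 4, NSG 2 weeks replicates 2 and 3, hHGF-NSG naive replicate 3 and hHGF-NSG 2 weeks replicate 2 (0.99 to 1.42, adjusted p = 0.0507 to 0.22). The count at 6 weeks was 8, 8 and 10 without NSG 6 weeks replicates 1, 2 and 3 and 9, 6 and 8 without hHGF-NSG 6 weeks replicates 1, 2 and 3.

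In naive tumours 6 mouse genes were lower in hHGF-NSG and none higher (unadjusted p < 0.05 for 1437 genes, and 0 called by limma voom). H2-T22, an MHC class I gene of a family that may share reads, had 8.51 ± 4.12 and 1.38 ± 0.86 FPKM (-1.96, SE 0.31, adjusted p = 0.027). This call ended without NSG naive replicate 3 (-1.66, adjusted p = 0.132), NSG naive replicate 4 (-1.90, adjusted p = 0.124) and hHGF-NSG naive replicate 1 (-1.67, adjusted p = 0.0749), within 0.000614 to 0.832 over all settings. Prorsd1 (-1.35, adjusted p = 0.0449) was not called without any 1 of 15 libraries (-1.42 to -1.19, adjusted p = 0.051 to 0.16), which were all but the library labelled NSG naive replicate 1, NSG 2 weeks replicates 1 and 2, NSG 6 weeks replicate 3 and hHGF-NSG naive replicate 3. Without the library labelled NSG naive replicate 1 the naive count was 117, and without NSG naive replicates 3 and 4 and hHGF-NSG naive replicate 3 it was 0, 0 and 42.

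The response to treatment differed between hosts for 3 mouse genes: Tnn (-2.88 and -3.33 for 2 and 6 weeks, adjusted p = 0.0473) and, chosen after their values were seen, Mir7013 (adjusted p = 0.000843) and Gm45738 (adjusted p = 0.0473). Leaving out the library labelled NSG naive replicate 1 gave 8 genes, leaving out hHGF-NSG 6 weeks replicate 1, 2 or 3 gave 0. A single gene was called on leaving out NSG naive replicate 3, NSG 2 weeks replicates 2, 3 or 4, NSG 6 weeks replicates 1 to 3, hHGF-NSG naive replicates 1 to 3 or hHGF-NSG 2 weeks replicates 1 to 4.

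The fixed mouse lists differed between hosts with the preset correlation only. Adipocyte genes were higher in hHGF-NSG (adjusted p = 0.0153, 7.77e-07 and 0.00441 in naive tumours, at 2 and at 6 weeks, with a median of 1.01 at 2 weeks, and adjusted p = 0.538, 0.288 and 0.518 with an estimated correlation). Cell cycle genes were lower, with adjusted p = 5.26e-07 in naive tumours and 7.62e-11 at 2 weeks, where 1 was called lower and 5 over the list alone (adjusted p = 0.144 and 0.0732 with an estimated correlation). Neutrophil genes were lower too, with adjusted p = 0.000375 and 9.57e-05 in the same states (adjusted p = 0.144 and 0.11 with an estimated correlation). Red blood cell genes were lower in hHGF-NSG naive tumours (median -0.78) and higher at 2 and 6 weeks (0.73 and 0.94), with adjusted p = 0.0117, 0.00101 and 0.00101 (adjusted p = 0.336, 0.217 and 0.217 with an estimated correlation). Myofibroblast, extracellular matrix and fibroblast genes were lower, with adjusted p = 1.06e-05, 0.000944 and 0.00381 at 2 weeks and 0.0444, 0.0396 and 0.000343 at 6 weeks (adjusted p = 0.25, 0.36, 0.379, 0.538, 0.538 and 0.288 with an estimated correlation). Dendritic cell genes (lower, 0.000534) and Schwann cell genes (higher, 0.00941) at 2 weeks, endothelial (2.37e-05), mast cell (0.00334) and Schwann cell genes (0.00278, all higher) at 6 weeks and skeletal muscle genes (lower, 0.021) in naive tumours had adjusted p = 0.0869, 0.288, 0.178, 0.288, 0.229 and 0.288 with an estimated correlation.

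Several of these list results ended with the preset correlation when a library was left out. In naive tumours NSG naive replicate 4 carried that of skeletal muscle genes (adjusted p = 0.652 without it, and 0.0607 without hHGF-NSG naive replicate 3). That of adipocyte genes ended without NSG naive replicate 4 (0.666) or hHGF-NSG naive replicates 2 and 3 (0.3 and 0.211). That of red blood cell genes ended without NSG naive replicates 3 and 4 (0.0733 and 0.0566) or hHGF-NSG naive replicate 3 (0.305). At 2 weeks Schwann cell, fibroblast and matrix genes lost theirs without hHGF-NSG replicates 1 (0.105), 2 (0.0601) and 3 (0.0513), in this order. At 6 weeks matrix genes lost theirs without NSG replicates 2 and 3 (0.151 and 0.104) or hHGF-NSG replicates 2 and 3 (0.105 and 0.108), and mast cell genes without hHGF-NSG replicate 3 (0.105). Myofibroblast genes lost theirs without NSG naive replicate 3 (0.0571), NSG 6 weeks replicates 2 and 3 (0.0675 and 0.116), hHGF-NSG naive replicate 1 (0.0592) or hHGF-NSG 6 weeks replicate 3 (0.536).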

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

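The tests below of host genes called at both times, a tumour mixture and neighbouring host genes were chosen only after the results were seen. Those of host genes called at 1 time and other sample splits were written first. A library is listed here when its value lay far outside those of the other libraries of its group. This held for 60 of 800 groups (7.5%), where chance gives about 1 in 20, so a large part of the values below may be chance.

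HGF in the library labelled NSG naive replicate 1 was 0.32 FPKM, where the other NSG naive libraries had 0 to 0.0061. A wrong host label predicts mouse genes at hHGF-NSG levels. Over 39 mouse genes called between the treated hosts at 1 time, this library was nearer the mean of the treated hHGF-NSG libraries for 56.4%, against 23.1% and 25.6% in NSG naive replicates 3 and 4. This missed the bound of 66% fixed for it, which the hHGF-NSG naive libraries missed too (59 to 61.5%). Over the 25 genes called at both times it was nearer for 20 (80%), against 3 and 3 in NSG naive replicates 3 and 4 and 22, 20 and 23 in the hHGF-NSG naive libraries. Its median position was 0.93, where 0 is the mean of treated NSG and 1 that of treated hHGF-NSG libraries, against 0.01 and 0.09 and 0.91 to 1.15. A wrong host label may thus be the cause. A swap with an hHGF-NSG naive library was excluded, as none of these was out of place (80% or more). A mixture with an hHGF-NSG tumour would leave 20 to 80% of the NSG level in genes lower in hHGF-NSG at both times. Over 21 such genes the median was 13.4% (quartiles 1.6 and 37.2). With no such values for hHGF-NSG naive libraries, a mixture could not be told from a wrong label. No biological explanation was tested.

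The mouse genes called between hosts at 2 or 6 weeks may differ by strain, as genes of a shared chromosome segment would. Of 64 such genes 22 had another within 2 Mb, against a median of 10, a 95th percentile of 17 and a highest of 26 in 10000 random draws, of which 32 had as many. Among the 64 genes with the smallest p for NSG at 6 weeks against naive, 20 had such a neighbour, so the neighbours alone hardly set the host genes apart. All 25 genes called at both times had 1 sign in the 3 states, and 29.7% of the 64 genes were pseudogenes, against 5.2% of all tested genes (Fisher exact two-sided p = 2.61e-10), where reads shared between copies might add to the differences. Segments around H2-D1 and H2-T23 on chromosome 17 and Shc1 and Pmvk on chromosome 3 were among them, and the effect of human HGF itself on these genes could not be separated from strain.

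On regrouping the libraries, the real split had the most calls for human NSG at 2 and 6 weeks. There 1 of 35 splits had as many (8989 against 1 in the highest other, and 9234 against 108). The real split led for human hHGF-NSG at 2 weeks too (1 of 35, 8673). A split that set hHGF-NSG 2 weeks replicate 1 with the naive samples called 5891. The real split also led for human and mouse 6 against 2 weeks (1 of 100, 3709 against 532 and 1505 against 3). For mouse NSG, hHGF-NSG and hosts at 2 weeks 1 of 35 had as many (1115 against 458, 1008 against 190 and 53 against 3). Chance was unlikely for all these but not excluded, as ranks were not adjusted over the comparisons. The 10 splits of 3 against 3 samples were too few for human hHGF-NSG at 6 weeks (8227 against 1), mouse NSG at 6 weeks (2486 against 1), mouse hHGF-NSG at 6 weeks (2541 against 2) and mouse hosts at 6 weeks (36 against 4), each with 1 split, and for mouse hosts in naive tumours, with 5 (6 against 36). Chance may explain human hosts in naive tumours (5 of 35, 3 against 1129), where NSG naive replicates 3 and 4 with hHGF-NSG naive replicate 3 called many times more, a structure of the samples other than host. Chance may also explain the mouse difference in response (16 of 100, 3 against 5). For human hosts at 2 weeks (35 of 35) and 6 weeks (35 of 35) and the human difference in response (100 of 100) no gene was called, so every split had as many calls and the splits decided nothing.

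In naive NSG tumours replicate 1 had CCDC188 at 0.183 FPKM (others 0), INSR at 0.65 (0.904 to 0.946) and SESN1 at 2.35 (2.92 to 2.97). Replicate 2 had CROCC2 at 0.0106 (0), TGFBI at 2.38 (8.5 to 8.78), PLAU at 7.54 (24.9 to 26.4), PIK3IP1 at 3.38 (4.09 to 4.23), COL1A1 at 8.89 (27.6 to 30.8) and the interferon list mean at 2.14 (2.47 to 2.53) in log2(FPKM + 1). Replicate 3 had AKAP12 at 31 (37 to 37.4).

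In NSG at 2 weeks replicate 1 had ADM at 1.88 FPKM (others 0.497 to 0.65), IGFBP3 at 2.22 (1.54 to 1.65) and XBP1 at 288 (265 to 268), replicate 2 IER3 at 15.9 (others at least 19.8) and the epithelial list mean at 6.96 (6.79 to 6.81), and replicate 3 CROCC2 at 11.7 (17 to 18) and HMGCS1 at 12.1 (9.98 to 10.1). At 6 weeks NSG replicate 1 had MYBL2 at 0.707 (1.25 to 1.34) and replicate 2 SRM at 8.42 (10.8 to 10.9) and CDH2 at 3.66 (2.54 to 2.58). Replicate 3 had HGF at 0.0468 (0 to 0.00741), RSPH1 at 43 (20.7 to 24), C5orf49 at 18.6 (11.1 to 11.7), PIP at 53.4 (27.3 to 28.5), IFIT1 at 2.22 (1.07 to 1.11) and SESN1 at 8.73 (5.98 to 6.35). Replicate 4 had ADM at 1.33 (0.0568 to 0.241), MUC5B at 3.2 (2.21 to 2.32), SLC2A3 at 0.0852 (0 to 0.0125), VIM at 3.6 (1.64 to 1.87), PLAU at 8.97 (3.8 to 4.44) and MET at 15 (10.9 to 11.5). In hHGF-NSG at 2 weeks replicate 1 had HMGCS1 at 14.8 (10.3 to 10.8), replicate 2 CDC20B at 117 (97.6 to 99.5) and TAP2 at 0.522 (0.768 to 0.811), replicate 3 MYBL2 at 1.7 (2.55 to 2.65) and BOP1 at 23.4 (21.9 to 22.2) and replicate 4 HPN at 1.8 (1.33 to 1.41).

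Of the mouse genes in NSG at 2 weeks, replicate 1 had Saa3 at 10.9 FPKM (others 2.56 to 3.99) and replicate 2 Kit at 1.47 (0.936 to 1.02) and the adipocyte list mean at 5.23 (6.26 to 6.29). Replicate 3 had Omd at 11.6 (7.26 to 7.53), Cxcl1 at 0.89 (0), Retnlg at 1.13 (0), Tgfb3 at 176 (127 to 134) and the mast cell list mean at 0.65 (1.78 to 1.9), and replicate 4 Mmp13 at 11.6 (1.87 to 2.87), Acp5 at 65.4 (45.3 to 48.7) and Esrp1 at 2.11 (0.48 to 0.741). In hHGF-NSG at 2 weeks replicate 1 had Mcpt8 at 0.307 (0), Retnlg at 1.03 (0) and the fibroblast list mean at 7.93 (6.95 to 7.11), and replicate 4 Mmp10 at 3.14 (0.201 to 0.582) and Cnn1 at 8.56 (1.01 to 2.01). Replicate 3 had Tcf15 at 24 (6.13 to 8.69), Cox8b at 96.1 (15 to 20.4), Hbb-bs at 289 (127 to 153), Krt19 at 0.373 (0) and Hbegf at 8.6 (3.29 to 4.13). A difference in response between the hosts put Tnn (adjusted p = 0.0473), Mir7013 (0.000843) and Gm45738 (0.0473) on this list.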

How the results depend on the processing

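No result reversed its direction. Of the calls of named genes 18174 were the same and 722 weaker when each library was left out, as were 872 and 24 with limma voom, 895 and 1 with rescaling, 819 and 77 without the filter, 847 and 49 with a pseudocount of 0.1 and 856 and 40 with the replicate block. For list tests the counts same, weaker and stronger were 6050, 68 and 106, then 294, 2 and 0 with rescaling, 260, 2 and 34 without the filter, 287, 4 and 5 with the pseudocount and 279, 4 and 13 with the replicate block. For the counts between hosts, human naive (3) became 5 with the pseudocount, 25 without the filter, 1 with the replicate block and 0 to 40 without 1 library. Human 2 weeks (0) became 2 without the filter and 0 to 1 without 1 library, 6 weeks (0) 1 without the filter, 2 with voom and 0 to 8, and the difference in response (0) 9 without the filter and 0 to 7. Mouse naive (6) became 13 with the pseudocount, 13 without the filter, 0 with the replicate block, 0 with voom, 2 with thinned reads and 0 to 117. Mouse hosts at 6 weeks (36) became 15, 22 with the replicate block, 73 with voom, 17 with thinned reads and 6 to 54, and the difference in response (3) 0 with the pseudocount, 1 with rescaling, 1 with voom and 0 to 8. Mouse 6 against 2 weeks (1505) became 944 with the replicate block and 931 to 1728, NSG 2 weeks (1115) 666 thinned and 655 to 1214, hHGF-NSG 2 weeks (1008) 581 thinned and 483 to 1132 and hHGF-NSG 6 weeks (2541) 1641 to 2664. The overlap at 2 weeks in mouse became 103 higher and 169 lower genes thinned, and 103 to 172 and 175 to 312 without 1 library. HGF differences without 1 library were 0.089 to 0.251 in naive tumours (highest without the library labelled NSG naive replicate 1), 0.203 to 0.277 at 2 weeks and 0.31 to 0.543 at 6 weeks. Without an NSG library exact p was 0.0571 at 2 weeks, while 1 library less at 6 weeks allows no call. Voom and thinned reads were chosen after seeing the data, and the cause was not tested, save that thinning shows a part due to depth. Libraries of equal number were not more alike (median correlation -0.02 over 51 human pairs against 0.02 over the others, and -0.01 over 43 mouse pairs against 0), so the replicate block holds no known pairing.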

Other observations

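The multiciliated cell and circadian clock lists, the clock tests and the cilia scaling test were chosen only after the results were seen. The test of mouse reads in cilia genes was written before it was run. All 23 measured genes of multiciliated cells, of 27 listed, rose in the tumour cells in both hosts at both times, with median log2 changes of 2.50 and 2.69 at 2 weeks and 1.68 and 1.96 at 6 weeks (adjusted p = 0.000305, 0.000305, 0.00103 and 0.000704 with an estimated correlation). FOXJ1, the transcription factor that drives motile cilia, had mean FPKM of 19.3, 436 and 117 in NSG and 17.8, 485 and 163 in hHGF-NSG (log2 changes 4.43 and 4.70 at 2 weeks, 2.52 and 3.13 at 6 weeks). CCNO, which cells need to form many cilia, rose by 4.60 and 4.63 at 2 weeks and the dynein chain DNAI1 by 4.41 and 4.43. From 2 to 6 weeks all 23 fell, 22 without hHGF-NSG 6 weeks replicate 1 (median -0.96, adjusted p = 0.000284). Between the hosts no gene of the list was called, but the list as a whole was higher in hHGF-NSG at 2 weeks (median 0.16) and 6 weeks (median 0.2), with adjusted p = 0.0424 at both with an estimated correlation, and not in naive tumours (0.05, adjusted p = 0.989). Host cells were excluded as the source of these reads, as the median of mouse reads in the listed genes at 2 weeks was 0% of the median of 1246.5 human reads. A scaling effect, which would move all genes of a library alike, was excluded too. The median change of the listed genes was 1.17 or more above the 95th percentile of the other 16006 genes in either host (1.33 and 1.41), and the lowest listed gene had 1.43 and 1.63.

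Clock genes moved together in tumour and host tissue from 2 to 6 weeks. Of 17 human clock genes measured 11 rose and 1 fell (median 0.96, adjusted p = 0.000305 with an estimated correlation), and of 18 mouse genes 10 rose and 3 fell (median 0.82, adjusted p = 0.00103). In the tumour cells the repressors NR1D1, NR1D2, PER3, PER1 and CIART rose by 2.62, 1.56, 1.62, 1.47 and 1.43, and in the host tissue Dbp, Tef, Per3 and Nr1d1 rose by 1.38, 1.17, 0.99 and 0.94. ARNTL, the activator that peaks opposite to NR1D1, fell by 0.44 in the tumour (adjusted p = 5.3e-06) and Arntl by 1.38 in the host (adjusted p = 0.000303). Its log2 change of -0.44 against the rise of NR1D1 excluded scaling as the cause. Collection at another time of day predicts the same direction in both species, and 9 of the 10 clock genes called in both tables had it, so this may be the cause. At 2 weeks against naive 4 of 5 such genes in NSG and 0 of 2 in hHGF-NSG had it. There 6 and 5 of the mouse clock genes rose and 1 and 0 fell (adjusted p = 0.0462 and 0.0271 with an estimated correlation), while 7 and 6 human ones rose and 6 and 6 fell (0.989 in either host). The times of collection are not in the labels and the 6-week treatment itself could do the same. No biological explanation was tested.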
